A study of Mus musculus with 6 samples.

How the data were processed

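Total RNA was extracted with Trizol from sorted mouse bone marrow progenitors, amplified with the WT-Ovation Pico system, converted to sense-strand cDNA and labelled with biotin for hybridisation to 1-colour arrays, per the labels' protocols. Each of 6 arrays held 1 sample, 3 per genotype, and the labels call them biological replicates without saying how many animals each held. The deposited values are on the log2 scale and carry 2 decimals, and RMA (background correction, quantile normalization between arrays and summary over the probes of a probe set) is named in the submitters' processing notes. Its software, version and settings are not given in the sources used here, and the log2 scale was read from the values. Scan dates, hybridisation batches and detection p-values were not used here. The number of arrays limits the precision, and RMA compresses differences of dim probe sets.

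The 25668 probe sets were named through the platform annotation, which can be old. It gave 1 gene for 20777 of them, several genes for 232 and none for 4659. Symbols were compared through Entrez identifiers with a table of RefSeq genes on GRCm38.p6, and 0 changed. That table also gave chromosome membership and the start positions that set gene order, and its coordinates were used for nothing else. The 564 genes with several probe sets were represented by the one with the highest mean over all arrays, so that 19661 genes were tested, with no filter on dim probe sets.

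Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so single genes were tested only in the limma model. Gene lists for the lineages around this gate and for technical controls were written before the data were examined. Of 21 lists, 20 were tested with limma's camera at a preset correlation of 0.01, and the sex-linked genes served only as a check. Camera with an estimated correlation and fry, which tests whether the genes of a set move on balance in 1 direction, were run beside it. None of the lists passed camera with an estimated correlation (0 of 20). That version also refers its statistic to the 4 residual degrees of freedom of the fit, far fewer than with the preset. List members were also adjusted over the list alone.

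The named genes were fixed by a rule before the data were examined. It took Zfpm1, Gata1 and Gata2, then the 12 largest increases and the 12 largest decreases among called genes whose genotypes did not overlap. Per list it took up to 4 members past the threshold over all genes (the 2 highest and 2 lowest) or, failing that, past it over the list alone, and otherwise the 1 with the smallest p. Predicted gene models and olfactory and vomeronasal receptors were skipped. Other genes are named as further members of a list or because their values stood out, and were chosen after their values were seen.

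The scripts were tested on simulated data with the real gene means, the residual SDs dealt at random to other genes, and noise drawn independently per gene. Of 50 genes changed by a log2 size of 0.5, 1, 1.5 and 2, limma recovered 16, 41, 48 and 50, and it called 9 of 19461 unchanged genes. Camera called 7 of 200 unshifted lists at an unadjusted p under 0.05, and 20 of 20 lists shifted by 0.3. The simulated genes were independent, so these counts do not show how camera errs on lists of correlated genes.

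Alternatives fixed beforehand were quantile normalization repeated, centring on array medians, leaving out the dimmest genes, averaging probe sets, testing all probe sets, an intensity trend, array weights, the replicate number as a block, other thresholds and leaving out each array in turn. A term for arrays with low Y-linked values and a comparison without both such arrays were chosen after seeing the data. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.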

Results

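Gene expression was measured in megakaryocyte-erythroid progenitors, the bone marrow cells that give rise to red cells and platelets, from mice with 2 intact Fog1 alleles (Fog1+/+) and from mice homozygous for a Fog1 knock-in (Fog1ki/ki). The cells were sorted as lineage-negative, Kit-positive, Sca1-negative and CD34-negative cells with low FcγRII/III. FOG1, encoded by Zfpm1, is a cofactor of the transcription factor GATA1. Each genotype had 3 arrays, described as biological replicates. The labels do not say what the knock-in changes. From general knowledge of the study, the altered FOG1 no longer binds the NuRD chromatin complex, and the comparison asks which genes depend on that contact. The array medians lay between 6.02 and 6.15 on the log2 scale. Correlations across genes were 0.993 to 0.994 among the Fog1+/+ arrays, 0.988 to 0.992 among the Fog1ki/ki arrays and 0.988 to 0.991 between genotypes, where genes are not independent replicates.

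No difference was detected in the transcript of the targeted gene. Zfpm1 measured 7.57, 7.37 and 7.80 in the Fog1+/+ arrays and 7.65, 7.50 and 7.73 in the Fog1ki/ki arrays, a log2 difference of 0.05 (SE 0.13, limma adjusted p = 0.948). The labels do not say what the knock-in changes, so this level was not used to check the genotype labels. Gata1 had a log2 difference of -0.29 (SE 0.11, limma adjusted p = 0.435) and did not pass the test. Gata2, which encodes a related transcription factor of stem cells and mast cells, was 2.20-fold higher in Fog1ki/ki, at 8.39 ± 0.34 against 7.25 ± 0.11 (SD, n = 3 each, limma adjusted p = 0.0164). The Gata2 call was lost without Fog1+/+ replicate 1, 2 or 3 (adjusted p = 0.0876, 0.0629 and 0.0635) and without Fog1ki/ki replicate 3 (adjusted p = 0.0579). Its log2 difference stayed between 0.97 and 1.31 in all 15 alternative settings run.

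The genes with the largest increases in Fog1ki/ki included several that are known from mast cells. Ms4a2, the beta chain of the high-affinity IgE receptor, was 13.9-fold higher, at 8.53 ± 0.68 against 4.74 ± 0.07 on the log2 scale (SD, n = 3 each, limma adjusted p = 0.000731). Rgs13, a regulator of G protein signalling, was 7.04-fold higher (limma adjusted p = 2.69e-05). In Fog1+/+ both genes lay below the lower quartiles of the arrays (4.81 to 4.92), at 4.74 and 3.87, and no test of signal above background was used, so these folds are ratios of RMA values that rest on a dim group. Alox5ap, the protein that presents arachidonic acid to 5-lipoxygenase for leukotriene synthesis, was 6.16-fold higher (limma adjusted p = 0.00156), and Alox5, the lipoxygenase itself, was 2.53-fold higher (limma adjusted p = 0.0221).

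Of the 37 measured mast cell genes, 8 rose over all genes tested, 0 fell and 29 did not pass in limma, and at an unadjusted p under 0.05 the counts were 12 higher and 1 lower. Adjusted over the list alone, 10 rose and 1 fell, the one that fell being Kit. Besides the genes above, the 8 comprised the granule membrane protein Cd63 (log2 difference 1.40), the heparin-modifying enzyme Ndst2 (1.34), Gata2 and the signalling adaptor Lat (0.57). The list as a whole lay higher than the other genes (median log2 difference 0.14, mean 0.56, camera adjusted p = 6.89e-09, limma). That call was not past the threshold with the correlation estimated from the data (adjusted p = 0.0869 with an estimated correlation). The estimate, 0.01625, lay close to the preset 0.01, so the change in correlation was small. The version with an estimated correlation has 4 degrees of freedom, far fewer than with the preset. The list passed fry (adjusted p = 0.00675). The alpha chain of the IgE receptor, Fcer1a, had a log2 difference of 1.91 (SE 0.46, limma adjusted p = 0.147) and Gzmb one of 1.27 (SE 0.39, limma adjusted p = 0.296). In Fog1+/+ the mean of Fcer1a, 4.63, lay below the lower quartiles of the arrays. Granule proteases and the histamine-forming enzyme of mature mast cells showed smaller differences that did not pass, with log2 values of 0.53 (SE 0.30) for Cpa3, 0.21 (SE 0.12) for Mcpt4, 0.07 (SE 0.08) for Tpsb2 and 0.06 (SE 0.11) for Hdc. Fog1ki/ki replicate 1 stood apart in Cpa3, at 5.65 against 4.56 and 4.31 in the other Fog1ki/ki arrays, and in the basophil protease Mcpt8, at 7.40 against 5.50 and 5.44.

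**Figure D1:**
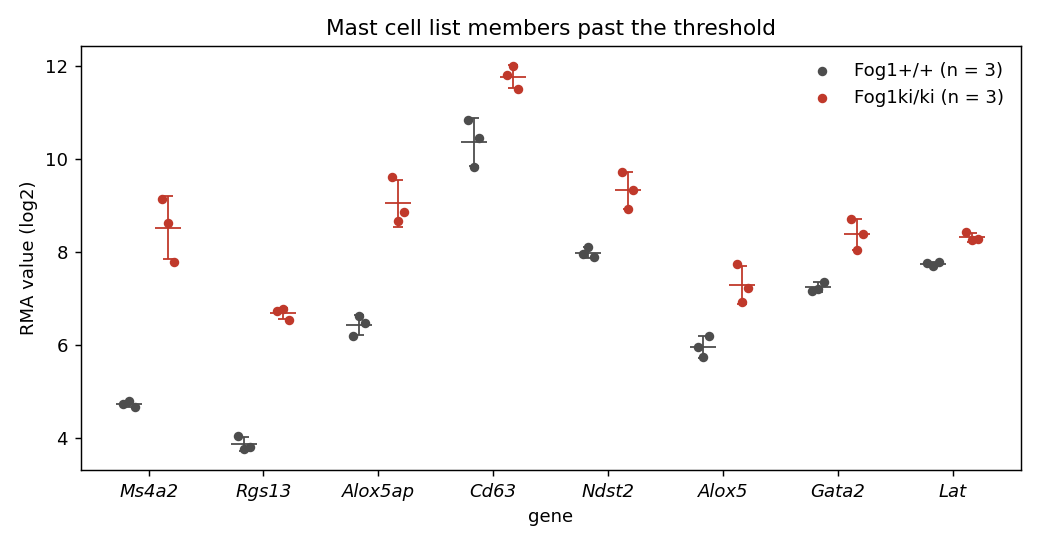
RMA values on the log2 scale (vertical axis) of the 8 mast cell genes past the threshold over all genes (horizontal axis), for 3 Fog1+/+ arrays (grey) and 3 Fog1ki/ki arrays (red). Points are arrays, and the horizontal and vertical lines are the mean and SD. For Ms4a2 the means were 4.74 and 8.53, and in each gene the arrays of the genotypes did not overlap.

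Other genes with large increases belonged to none of the lists. Lonrf2, a RING finger protein, was 8.67-fold higher (limma adjusted p = 5.35e-05). Trim9, a ubiquitin ligase best known from neurons, was 5.49-fold higher, and Mpped2, a phosphoesterase, was 4.50-fold higher. Log2 differences between 1.62 and 1.85 were measured for Nebl, the fatty acid desaturase Scd1, the guanine nucleotide exchange factor Dock8, the lactate dehydrogenase subunit Ldhb, the carboxypeptidase Cpd and the muscle LIM protein Csrp3. Nebl stood at 1.85 with its brightest probe set and at 1.02 with its probe sets averaged. Scd1 was not past the threshold without Fog1+/+ replicate 1 (limma adjusted p = 0.0507) or Fog1ki/ki replicate 2 (limma adjusted p = 0.0585). Trim9 lay within 10 tested genes of Atl1 and Map4k5, which fell, and Dock8 lay near Smarca2, which rose.

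The genes with the largest decreases were of varied function. Mt2, a metallothionein, was 5.02-fold lower (8.91 ± 0.59 against 11.23 ± 0.15, SD, n = 3 each, limma adjusted p = 0.00461), and its neighbour Mt1 fell by 1.20 on the log2 scale. Galnt7, which starts O-linked glycan chains, was 5.02-fold lower (limma adjusted p = 0.000325). The phospholipid-binding protein Anxa5 was 4.67-fold lower (limma adjusted p = 3.68e-05), and Grb10, an adaptor of the insulin receptor, was 4.16-fold lower. Prelid2 had a log2 difference of -1.97, Cecr2, a bromodomain protein, one of -1.76, and Mfhas1 and Sh2d4a ones of -1.69 and -1.67. Log2 differences between -1.60 and -1.45 were measured for the glutathione transferase Gsta4, Sccpdh, the connexin Gjb2 and the manganese transporter Slc30a10. Mt2, Galnt7, Mfhas1 and Sh2d4a lie on the chromosome that carries Zfpm1, and Sccpdh and Sh2d4a each lay within 10 tested genes of other genes past the threshold. Sccpdh was not past the threshold without any 1 of the Fog1+/+ arrays or of Fog1ki/ki replicates 2 and 3 (limma adjusted p from 0.0870 to 0.149), nor Slc30a10 without Fog1+/+ replicate 2 or 3 or Fog1ki/ki replicate 1 or 2 (limma adjusted p from 0.0869 to 0.162).

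In all, 152 of 19661 genes passed limma's test at an adjusted p under 0.05, of which 74 were higher and 78 lower in Fog1ki/ki, and 66 differed by at least 2-fold (36 higher, 30 lower). With each array centred on its median the counts were 49 higher and 75 lower. In each of the 152 genes the arrays of the genotypes did not overlap, as in 14.8% of all genes, where chance gives 10%. The count fell to 60, 83 and 60 without Fog1+/+ replicate 1, 2 and 3 and to 82 without Fog1ki/ki replicate 2. Replicate 3 of each genotype had much lower values of the Y-linked genes Eif2s3y (3.21 and 3.46, against at least 9.29 in the other arrays), Uty (3.96 and 3.85, against at least 8.18) and Kdm5d (5.32 and 5.12, against at least 8.72) and high Xist (11.02 and 11.03). With a term for these 2 arrays, chosen after the data were seen and keeping all 6, 127 genes passed, 116 of them among the 152, and of 30 named genes past the threshold 1 lost its call (Xk). Without these 2 arrays, also chosen afterwards and with 2 left per genotype, 24 genes passed, 22 of them among the 152. In that comparison 16 of the 30 named genes lost their call, with log2 differences that stayed at 82.7% to 116% of those over all arrays: Gata2, Alox5ap, Trim9, Mpped2, Dock8, Ldhb, Cpd, Csrp3, Mt2, Cecr2, Sccpdh, Slc30a10, Xk, Blnk, Adgrg1 and Chd3.

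**Figure D2:**
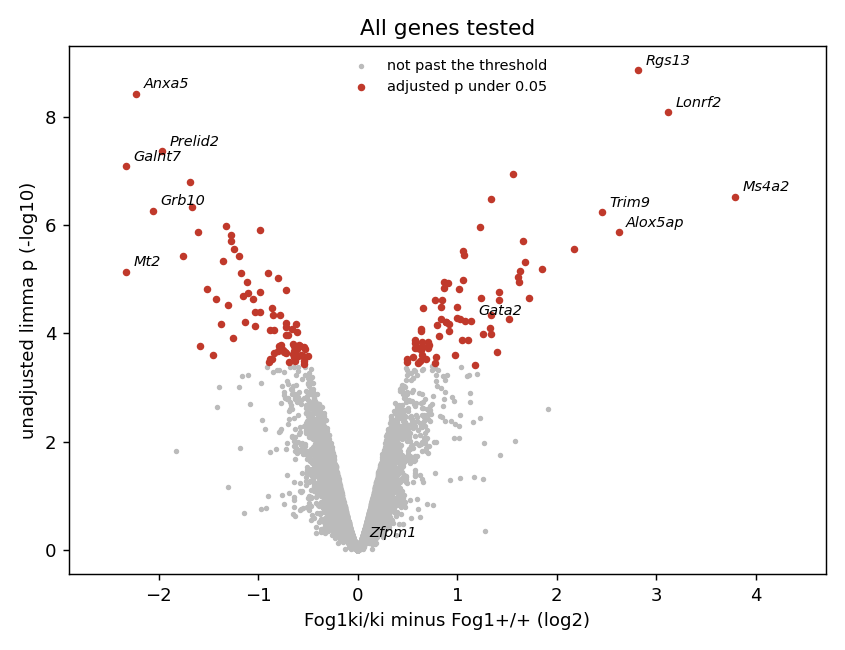
Log2 difference of Fog1ki/ki minus Fog1+/+ (horizontal axis) against the unadjusted limma p on a -log10 scale (vertical axis) for 19661 genes, 3 arrays per genotype. Each point is a gene, red where the adjusted p was under 0.05, which holds for 74 genes on the right and 78 on the left.

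Of 35 megakaryocyte and platelet genes, 1 rose over all genes and 34 did not pass, while 2 rose adjusted over the list alone. The gene past the threshold over all genes was Ltbp1, which binds latent TGF-beta, with a log2 difference of 1.06 (SE 0.10, limma adjusted p = 0.00259). The other was Plek, a platelet protein kinase C substrate, at 0.83 (SE 0.17, limma adjusted p = 0.0911). Pf4, the platelet chemokine, had a log2 difference of 0.97 (SE 0.29) and Itga2b one of 0.31 (SE 0.11), and neither passed. The list lay higher than other genes (median 0.11, mean 0.18, camera adjusted p = 0.00576), but not past the threshold with the correlation estimated (adjusted p = 0.163 with an estimated correlation). The estimate was -0.0269, below the preset 0.01, so correlation among the members does not account for the lost call. The version with an estimated correlation has 4 degrees of freedom, far fewer than with the preset, which goes with the larger p. The list passed fry (adjusted p = 0.000718).

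Of 32 erythroid genes, 1 fell over all genes and 31 did not pass, and 2 fell adjusted over the list alone. Xk, which carries the Kx blood group antigen, fell by 0.60 on the log2 scale (limma adjusted p = 0.0389). The Xk call was lost in 11 of 15 alternative settings, among them leaving out any 1 of the 6 arrays (limma adjusted p from 0.0742 to 0.202), quantile normalization repeated (0.0625), an intensity trend (0.0511) and a term for arrays with low Y-linked values (0.0681). The log2 difference of Xk stayed between -0.66 and -0.53 in all 15. Add2, a subunit of the membrane skeleton protein adducin, had a log2 difference of -0.49 (limma adjusted p = 0.0592). The erythroid list did not pass (median -0.05, camera adjusted p = 0.0592), but passed without Fog1+/+ replicate 1 (adjusted p = 0.0185), without Fog1ki/ki replicate 1 (adjusted p = 0.00203), with an intensity trend (adjusted p = 0.0457) and with array weights (adjusted p = 0.00611). It did not pass with the correlation estimated from the data (adjusted p = 0.576 with an estimated correlation). Neither did the 18 haem synthesis and iron genes (median -0.06, camera adjusted p = 0.187) or the 4 globin genes (median 0.02, camera adjusted p = 0.751) pass. The globin genes measured were Hba-x, Hbb-bh1, Hbb-y and Hbq1a, while Hba-a1, Hba-a2, Hbb-b1, Hbb-b2 and Hbb-bs had no probe set of their own. The haem enzyme gene Alad had a log2 difference of -0.36 and the globin gene Hbq1a one of 0.47, and neither passed over all genes, while Hbq1a was higher adjusted over the list alone. The Hbq1a means, 4.15 in Fog1+/+ and 4.62 in Fog1ki/ki, both lay below the lower quartiles of the arrays.

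None of the 38 cell cycle genes passed, over all genes or adjusted over the list alone (0 in limma in both, 1 higher and 4 lower at an unadjusted p under 0.05), while Mcm3, a replication licensing factor, had the smallest p (log2 difference -0.34, limma adjusted p = 0.177). The list lay lower than other genes (median -0.05, mean -0.08, camera adjusted p = 0.00859). The median turned to 0.02 with quantile normalization repeated (adjusted p = 0.907), and the call was lost with adjusted p = 0.451 with an estimated correlation. It was also lost without Fog1+/+ replicate 3 (adjusted p = 0.119), without Fog1ki/ki replicate 3 (adjusted p = 0.0836), without both replicates 3 (adjusted p = 0.306) and without the dimmest genes (adjusted p = 0.104). The list did not pass fry (adjusted p = 0.224). Grouping Fog1+/+ replicate 1 with Fog1ki/ki replicates 2 and 3 gave the list a smaller unadjusted camera p (0.000335) than the real genotypes did (0.00129).

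Of 17 genes of the NuRD complex and its FOG partners, 1 rose, over all genes and adjusted over the list alone, and 16 did not pass. Chd3, a helicase subunit of NuRD, was 2.09-fold higher (limma adjusted p = 0.00280), as was its neighbour Rnf227 (log2 difference 1.08). The helicase gene Chd4 had a log2 difference of -0.27 (limma adjusted p = 0.353), and the list as a whole did not pass (median -0.08, camera adjusted p = 0.237). Of 16 genes known to be repressed by GATA1, 1 rose, Gata2, and 15 did not pass. Adjusted over the list alone, Gata2 rose and 2 fell, Vim (log2 difference -0.68) and Kit (-0.38). The median of that list was -0.02 and its mean 0.06, of opposite sign (camera adjusted p = 0.974).

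Among 24 stem cell genes, Gata2 and Adgrg1, an adhesion receptor, rose and 22 did not pass, with 4 higher and 2 lower adjusted over the list alone (median 0.06, camera adjusted p = 0.191, fry adjusted p = 0.0303). Adgrg1, which lies on the chromosome that carries Zfpm1, had a log2 difference of 0.64 (limma adjusted p = 0.0195), lost without any 1 of the Fog1+/+ arrays or of Fog1ki/ki replicates 2 and 3 (limma adjusted p from 0.0630 to 0.106). In the list of 33 lineage transcription factors, 1 rose, Gata2, over all genes and adjusted over the list alone (median 0.03, camera adjusted p = 0.191). Of 21 B lymphoid genes, the adaptor Blnk rose (5.80 ± 0.09 against 4.80 ± 0.27, SD, n = 3 each, limma adjusted p = 0.0156), Cecr2 fell and 19 did not pass, with 1 higher and 1 lower adjusted over the list alone (median 0.05, camera adjusted p = 0.897). Cecr2 is a chromatin protein rather than a marker of B cells, and the Blnk call was lost without Fog1+/+ replicate 3 (limma adjusted p = 0.0604) or Fog1ki/ki replicate 2 (limma adjusted p = 0.0818). The Fog1+/+ mean of Blnk lay just below the lower quartiles of the arrays (4.81 to 4.92).

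Lists of markers of other cells, most of which a lineage-negative, Kit-positive gate is meant to remove, did not pass, nor did any of their members over all genes. The lists comprised 19 basophil and eosinophil genes (median 0.10, camera adjusted p = 0.0840), 28 neutrophil genes (median 0.01, mean -0.02, camera adjusted p = 0.745), 27 monocyte and macrophage genes (median 0.02, camera adjusted p = 0.440), 22 T and NK lymphoid genes (median 0.10, camera adjusted p = 0.294) and 12 non-haematopoietic genes (median 0.07, camera adjusted p = 0.239). Members with the smallest p were Prg2 (log2 difference 0.83), Retnlg (0.64), Fcgr2b (0.29), Cd3g (-0.28) and Krt8 (0.41), and Retnlg rose adjusted over the list alone. Without Fog1ki/ki replicate 1 the basophil and eosinophil list passed (median 0.165, camera adjusted p = 0.0272), as did Prg2 over all genes (limma adjusted p = 0.00891), and with each array left out in turn that median ran from 0.0417 to 0.165. An estimated correlation was used only over all 6 arrays, where this list had a camera adjusted p of 0.451. The 12 genes of the sorting gate had a median of 0.03 (camera adjusted p = 0.950), and of these Kit had a log2 difference of -0.38 and Cd34 one of 0.10, with 1 higher (Fcgr2b) and 1 lower (Kit) adjusted over the list alone. The 19 immediate early and heat shock genes had a median of -0.17 (camera adjusted p = 0.0840), with Klf6 at 0.87, Ier3 at 0.58 and Junb at -0.34, which made 2 higher and 1 lower adjusted over the list alone, and this list passed without Fog1+/+ replicate 1 (adjusted p = 0.0185). The 16 interferon response genes (median -0.08, camera adjusted p = 0.237, Rsad2 at 0.22) and the 17 ribosomal protein genes (median -0.04, camera adjusted p = 0.0840, Rpl34 at -0.17) did not pass either, and the latter passed with an intensity trend (adjusted p = 0.0240).

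**Figure D3:**
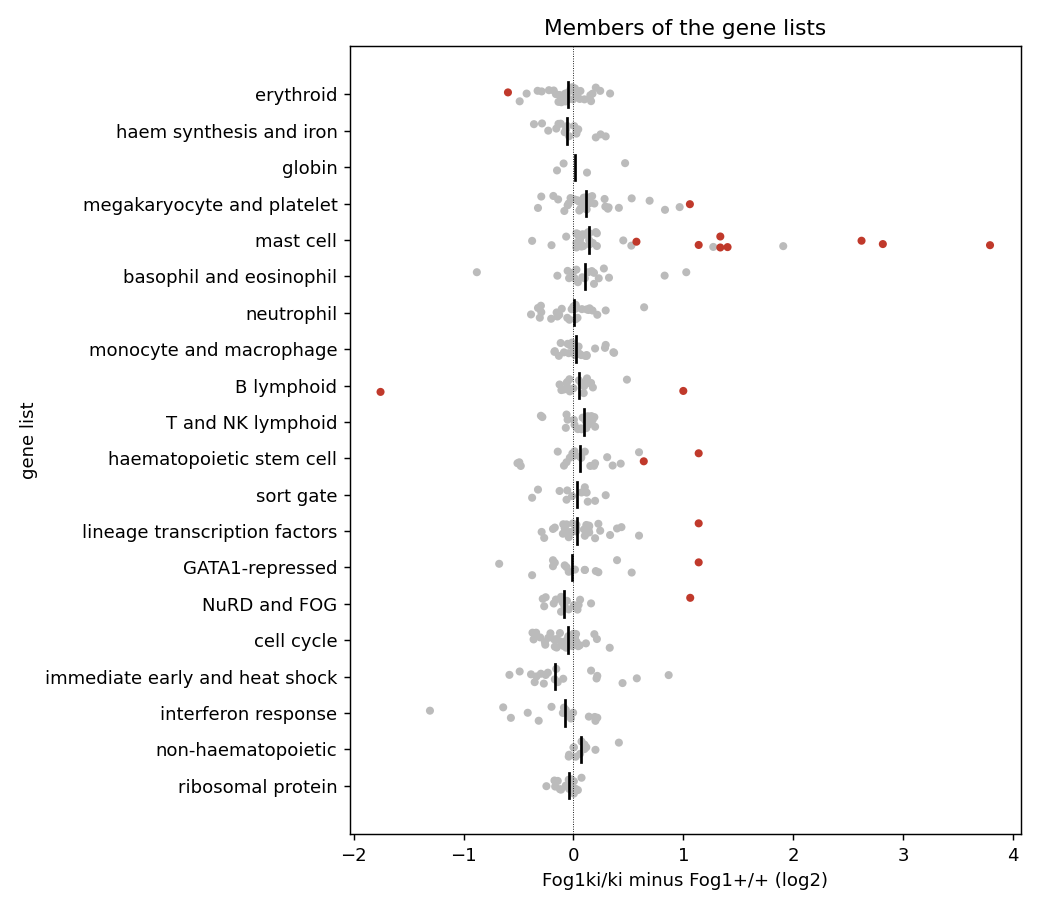
Log2 difference of Fog1ki/ki minus Fog1+/+ (horizontal axis) for the members of 20 gene lists (vertical axis), from 3 arrays per genotype. Each point is a gene, red where it was past the threshold over all genes, and the black bars are list medians, which run from -0.17 for immediate early and heat shock genes to 0.14 for mast cell genes.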

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

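In this part the tests of mature mast cells, basophils, granulocyte-macrophage and common myeloid progenitors, DNA around Zfpm1 and mixed sexes, and the draws matched on expression, were chosen only after the results they bear on were seen, those of mature mast cells and basophils as the whole cause after a first bound had left both open; the pairs of neighbouring genes and the splits of the arrays were fixed before.

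Among 4891 probe sets with no single gene name, which entered no comparison above, 5 were higher in Fog1ki/ki than in Fog1+/+ and 3 lower in the limma fit over all probe sets, with log2 differences from -1.42 to 1.78.

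The mast cell genes past the threshold had a median log2 difference of 1.37, and genotype is the biological explanation the design names. Granulocyte-macrophage or common myeloid progenitors in the gate are argued against as the whole cause, because 12 of their genes had a median of 0.0367. With 0.215 as 2 median standard errors this stayed below the bound of 0.343, which was set from the mast cell rise. That bound rests on genes picked for being called in these data. Cd34 and Fcgr3, among the 12, encode markers the sort selects against, so a smaller part stays open. Several of the 12 were also dim in Fog1+/+ (Cd34 4.37, Elane 5.04, Csf1r 5.07, Ctsg 5.09), where RMA compresses differences, while Mpo lay at 6.42. Mature mast cells as the whole cause are argued against, since each of 6 granule genes plus 2 standard errors stayed below 1.37, at most 1.13 for Cpa3, but a smaller part stays open under the first bound, with a median of 0.17 and a largest standard error of 0.30. Cpa3, Mcpt4 and Cma1 among them were dim in Fog1+/+, where RMA compresses differences. Basophils, most of which a Kit-positive sort is meant to remove, stay open over all arrays, with a median of 0.13 over 5 genes, because Mcpt8 (1.03, SE 0.44, highest in Fog1ki/ki replicate 1) reached 1.91 with 2 standard errors, while Prss34, Cd200r3, Il4 and Ccr3 differed by 0.13, 0.10, 0.19 and -0.05. Without that array Mcpt8 still differed by 0.38 (SE 0.10) and the basophil and eosinophil list passed (camera adjusted p = 0.0272). There Mcpt8, the highest of the 5 basophil genes, reached 0.575 with 2 standard errors, below the median of 1.26 of the called mast cell genes. The array was picked for its high Mcpt8 and Cpa3, so these values do not settle the question. Immature mast cell progenitors, which share Kit with the sorted cells, were not tested.

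The genes past the threshold lay over the whole genome, and the strain is given as B6.129, so that passenger DNA may differ between genotypes. DNA around Zfpm1 as the whole cause is argued against, since 7.89% of called genes lay on its chromosome against 4.81% of genes tested (Fisher's exact p = 0.0837). Of the 100 nearest genes 0 were called by limma, with 8 at an unadjusted p under 0.05. Over all genes 0.773% were called and 1882 of 19661 had such an unadjusted limma p, so the counts near Zfpm1 lay close to the background. Of the 12 called genes on that chromosome 8 were lower, among them Mt2, Galnt7, Mfhas1 and Sh2d4a, 4 of the 12 named largest decreases. For these genes linked DNA farther from Zfpm1 stays open. Called genes lay within 10 tested genes of each other in 23 pairs, where 10000 random draws gave a median of 11 and a central range from 6 to 19 (one-sided permutation p = 0.0024), and draws matched on expression gave 12 and from 6 to 20 (permutation p = 0.00730). This is consistent with blocks of another strain's DNA for the 29 genes in these pairs, and 11 pairs moved in opposite directions, but shared regulation of neighbours and paralogs such as Mt1 with Mt2 were not separated from it. Genotype itself stays open for all of the called genes.

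Fog1ki/ki replicate 2 held both Xist (9.13, against 5.62 ± 0.39 in the other 3 arrays with high Y-linked values) and Y-linked genes. Cells of both sexes in 1 sample could give this, and the Xist level would imply 25.1% female cells and Y-linked genes lower by a log2 difference of -0.42. The 3 Y-linked genes differed by a mean of -0.0622 (SD 0.23) from the other arrays with high Y-linked values and moved apart, with Eif2s3y at 0.13 and Kdm5d at 0.00, far from that value, and Uty at -0.32, near it. With 3 genes that disagree and a share that rests on Xist alone, this stays open. No biological explanation was tested.

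The 6 arrays can be split into 3 and 3 in 10 ways, so that the share of splits is never under 0.1. For genes past the threshold, 1 split gave as many as the real one, the real one itself, with 152 genes against 0 in limma in the highest of the others, where 506 to 1169 genes had an unadjusted p under 0.05. Every other split mixes the genotypes within its groups. A genotype difference there widens the spread within groups and lowers the count, so the 0 is not what unrelated groupings would give. For gene lists, 4 splits, the real one included, gave as many, with 3 lists in the real split and 5 in the highest of the others.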

How the results depend on the processing

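The sex term and the comparison without both arrays with low Y-linked values were chosen only after the data were seen. In the other settings that keep all arrays, 124 to 184 genes passed at an adjusted p under 0.05, and 226 at an adjusted p under 0.10. When all probe sets were tested, 115 probe sets passed. The 184 came with array weights, where Fog1ki/ki replicate 1 was weighted lowest (0.44). Leaving out 1 array gave 60 to 134 genes (28 to 62 higher, 28 to 79 lower), and leaving out both arrays with low Y-linked values gave 24 (14 higher, 10 lower), with fewer samples. Centring on array medians moved the log2 differences by -0.04 and left 49 higher and 75 lower. Of 30 named genes past the threshold, 13 kept their call in every setting that tested them (Rgs13 in 14 of 15, since it is among the dimmest genes) and 0 reversed. Zfpm1 ran from -0.0583 to 0.157 with 1 array left out. Lists past the threshold numbered 5 with an intensity trend, 0 with an estimated correlation (mast cell median 0.14, megakaryocyte 0.11), 3 with fry (2 shared, the other being the stem cell list) and 2 to 5 with 1 array left out. The erythroid list passed with a trend (-0.0483), with array weights (-0.0777) and without replicate 1 of either genotype, and ran from -0.0708 to -0.0167 with 1 array left out. Small list medians changed sign, and the cause was not tested except for centring, which moved every log2 difference by the same -0.04. With quantile normalization repeated they were globin -0.0307, neutrophil -0.0310, monocyte -0.0244, GATA1-repressed 0.0153, cell cycle 0.0225 and ribosomal protein 0.0175. With centring they were globin -0.0267, neutrophil -0.0367, monocyte -0.0233, sort gate -0.0133 and lineage transcription factors -0.0133. Without the dimmest genes they were globin -0.09 and monocyte -0.02. Without both arrays with low Y-linked values they were neutrophil -0.085, monocyte -0.01, B lymphoid -0.02, stem cell -0.015 and sort gate -0.0125. With 1 array left out the medians ran from -0.075 to 0.0233 for neutrophil, -0.00167 to 0.05 for monocyte, -0.0825 to 0.113 for globin, -0.00167 to 0.06 for B lymphoid, -0.0592 to 0.085 for GATA1-repressed and -0.0167 to 0.0792 for sort gate genes. With the sex-linked genes left out, arrays of the same replicate number correlated weakly within genotype-centred values (0.04, -0.03 and 0.03). In 2 of 3 pairs the Fog1+/+ array correlated best with the Fog1ki/ki array of its own number. So few pairs cannot show whether the numbers pair the arrays. In the sex-linked genes, replicate 3 of both genotypes had low Y-linked values. With the replicate block 133 genes passed, 108 of them shared. Among the named genes Xk and Adgrg1 then lost their call (limma adjusted p = 0.0981 and 0.0501) and Retnlg passed (limma adjusted p = 0.0487). Calls were fewest among dim genes, with 7, 52 and 93 among genes of low, middle and high expression, and the reason was not tested.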

Other observations

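The genes named in this part, and the families tested, were chosen only after the results were seen. Outside the lists, Tmsb4x, which encodes the actin-binding peptide thymosin beta 4, had a log2 difference of 1.56 (limma adjusted p = 0.000371), and the carbonic anhydrase gene Car13 one of 1.34 (limma adjusted p = 0.000731). The transcription factor gene Klf7 rose by a log2 difference of 1.26 and the neuroserpin gene Serpini1 by 1.61. Armcx2, Armcx6 and Arxes2, which lie within 10 tested genes of each other, rose by 1.52, 1.33 and 1.42. Among the genes that fell were the connexin gene Gja1 (-1.12) and its neighbour Hsf2 (-1.15), the cathepsin gene Ctsl (-0.85), and Npc2 (-1.03), which binds cholesterol in lysosomes.

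Of 611 gene families formed by shared symbol stems, 0 held more called genes than chance at an adjusted p under 0.05 in a one-sided hypergeometric test. The smallest p was that of Alox, with 2 of 7 members called, Alox5 and Alox5ap (unadjusted p = 0.00132, adjusted p = 0.807), whose products act in 1 pathway but are not related in sequence.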
